A study of Zea mays with 6 samples.

How the data were processed

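Messenger RNA levels were measured on 3 two-colour Agilent oligonucleotide arrays with 42034 maize probes each, which carried 6 RNA samples in 4 groups. Per the labels, whole anthers and laser-microdissected pre-meiotic cells of the inbred line W23 were each sampled as replicates 1 and 2, and the mac1 mutant and the mac1 heterozygote were each sampled once. Per the labels' protocols, RNA of whole anthers was extracted from frozen tissue with TRIzol, RNA of dissected cells was purified on a column for small samples, and all samples were linearly amplified and labelled with Cy3 or Cy5. How cells were chosen for dissection is not given in the sources used here. Array 1 carried whole anthers in Cy5 against pre-meiotic cells in Cy3 (replicate 1), array 2 carried pre-meiotic cells in Cy5 against whole anthers in Cy3 (replicate 2), and array 3 carried mac1 mutant cells in Cy5 against heterozygote cells in Cy3. The titles give an anther length of 700 µm for both W23 replicates, while another label gives 701 µm for replicate 2. The mac1 anthers were 1 mm long.

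Per the file headers, the deposited scanner files were written by Agilent Feature Extraction 10.5.1.1 and hold 1 array each. Their intensity columns give the median pixel brightness of each spot and of its local background in scanner units, not background-subtracted, and no mean spot signal. A second pair of deposited intensity columns holds the scanner software's processed signals, which per the file headers were background-subtracted and dye-normalized by linear and lowess steps. The submitters' processing notes name limma 3.8.3 and R 2.13. The authors' deposited value table holds one intensity column per sample on a linear scale. On log2 values, each of its columns correlated with its own labelled channel at 0.995 to 0.999 and with any other channel at no more than 0.971, which settled its direction. Its column medians were 62.8 and 63.6 for whole anthers replicates 1 and 2, 57.4 and 59.5 for W23 pre-meiotic cells replicates 1 and 2, 43.8 for the mac1 mutant and 46.0 for the heterozygote. Between 10005 and 21473 values per column were set to 0, and whether its columns were scaled between arrays stays unknown.

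The values used here were computed with R 4.3.3 and limma 3.58.1. The analysis plan had named mean spot signals, and the median signals were used because the files hold those. Background was corrected by normexp with an offset of 50 over all spots, and log2 ratios were normalized by loess within each array with control spots and outlier-flagged spots at weight 0. The offset draws the ratios of dim probes towards 0, so the ratio from the scanner's processed signals is given beside the main one for dim named genes. Control spots and the 8, 11 and 12 probe spots flagged as outliers on arrays 1, 2 and 3 were left out. No probe spot was saturated. A probe was tested in the W23 comparison if the scanner software called it well above background on both arrays in at least 1 of the compared groups, which left 33646 probes. On the mac1 array, 32266 probes were well above background in at least 1 channel. Where a group was not well above background on any of its arrays, the fold is a lower bound, computed per channel after loess and Aquantile scaling against, on each array, the higher of the lowest signal among probes well above background and the signal of the dim probe itself.

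The W23 ratios were turned to pre-meiotic cells over whole anthers and fitted with limma (lmFit and eBayes) on both arrays, with 1 residual degree of freedom and 4.87 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The dye effect cancels in the mean of the opposite orientations. With no dye term in the fit, it stays in the residual, so the SEs and p-values hold dye effects of a probe together with replicate spread. The ratio within an array treats the samples of a replicate number as a pair: they share an array, and per the series' design text they came from the same plants. Across the tested probes, the difference between replicates 1 and 2 in whole anthers correlated at 0.406 with that in pre-meiotic cells. The design text speaks of individual plants but does not say how many contributed, nor whether the dye-swapped arrays used separate RNA extracts. The p-values therefore measure only the spread between these arrays, dye effects included. If both arrays carried the same extracts, the SEs and p-values of the W23 comparison measure technical spread only. Arrays 1 and 2 lay on 1 slide in 1 scan, and array 3 lay on another slide in another scan, so slide, scan and experiment cannot be told apart. The mac1 comparison has 1 sample per group and its dyes were not swapped. It therefore has no test, and probes were described by a fixed size of at least 2-fold.

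The arrays name most probes by clusters of expressed sequence tags (TC numbers, 27161 probes) or by single sequence accessions. Only 21 probes carry a gene name, and 4 probes with 2 names (AM1 and AI676903) matched a table of maize genes of the assembly Zm-B73-REFERENCE-NAM-5.0. Of 23 gene lists fixed before the data were examined, among them lists for the anaerobic response, redox proteins, glycolysis, tapetum, epidermis and vascular tissue, 1 had members, the list of meiosis and recombination genes. It was tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. On the mac1 array its median was ranked among 10000 random lists of the same size matched on intensity. The rule for named genes, also fixed beforehand, took mac1, am1 and a few other anther genes where the files name them, the strongest called probes whose names or descriptions identify a gene, up to 3 members of each list, and, without descriptions, at most 2 sequence names each way. A gene with several probes is represented by its brightest probe, with disagreement stated. No probe is named mac1 in the files. ZmRAD21, the MuDR-type names and AI676903 lie outside the rule and were added after the values were seen, because the files or the gene table name them.

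Simulated ratios for the W23 comparison, over 33646 probes with known changes, were used to test the fit and its threshold. Their noise was independent between probes and drawn from the fitted limma prior, and the changes had both signs. Background correction, loess, dye effects and shared extracts were not simulated, so the shares below say nothing of errors from these. With 200 probes changed, 92% of changes of 1 on the log2 scale were called and 2% of changes of 0.5, and 16.1% of the calls were unchanged probes. With 11215 probes changed, 99.4% and 81.5% were called, and 3.21% of the calls were unchanged probes. The alternatives were other background corrections, the scanner's processed signals (already lowess-normalized) with median centring and no further loess, median centring of the main signals, Aquantile scaling, the deposited value table, other filters on dim probes, other variance priors, separate-channel fits without the array as a block or with the dye as a covariate, leaving out each sample, and subtracting from the mac1 array the mean red over green ratio per probe of the swapped arrays. That mean estimates the dye effect, but each orientation has 1 replicate, so it also holds differences between replicates.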

Results

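The study profiled maize anthers before meiosis. Pre-meiotic cells cut from W23 anthers by laser microdissection were compared with whole anthers of the same stage, which also hold the somatic cell layers (2 samples each), and pre-meiotic cells of a mac1 mutant were compared with those of a mac1 heterozygote (1 sample each). mac1 (multiple archesporial cells1) is a gene that limits how many cells of the anther become germ cells. Whole anthers had 84.3% and 82.45% of probes well above background in replicates 1 and 2, and W23 pre-meiotic cells 73.89% and 77.73%. The mac1 heterozygote had 72.9% and the mutant 64.4%. The correlation of observed with stated spike-in ratios was 0.9864, 0.9759 and 0.9955 on arrays 1, 2 and 3, with slopes of 0.913, 0.91 and 0.878. The number of arrays limits the precision of every value.

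The first comparison asked which transcripts differ between dissected pre-meiotic cells and the whole anther. Dissection and RNA extraction differed along with the cells, so cell type and sample preparation cannot be told apart in any of these differences. AM1 (ameiotic1), which maize cells need to enter meiosis, was higher in pre-meiotic cells on all 3 of its probes. Its brightest probe was higher by 1.11 ± 0.121 on the log2 scale (SE, 2 arrays, 2.15-fold, limma adjusted p = 0.00137), at 0.95 on replicate 1 and 1.27 on replicate 2. Its other probes were higher by 1.18 ± 0.121 (adjusted p = 0.00111, limma) and 0.40 ± 0.102 (adjusted p = 0.0285, limma). AM1 was dim in whole anthers, with a mean log2 intensity of 5.80 ± 0.0443 for the brightest probe (SD, n = 2) against 6.91 ± 0.182 in pre-meiotic cells. The scanner's processed signals, which carry no offset and were median-centred, gave log2 ratios of 3.91, 3.75 and 1.40 for the same probes, or 15.0-fold, 13.4-fold and 2.64-fold. In the fit to these signals even the sequences lowered most in the main processing had only limma adjusted p = 0.0467. That fit had little power, so a lost call there says little. The probe at 2.64-fold was not called (limma adjusted p = 0.0568). That probe also lost its call with median centring (log2 ratio 0.27, limma adjusted p = 0.258), with median centring over the tested probes (0.43, limma adjusted p = 0.101) and with the dye in place of the array (limma adjusted p = 0.111), and whichever of the 4 samples was left out (limma adjusted p = 0.0952 to 0.17). In the reference table AM1 corresponds to LOC100271891 (GRMZM5G883855).

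Genes of the cohesin complex, which holds sister chromatids together, gave mixed or lower values. ZmSMC1 and ZmSMC3 are core subunits of the cohesin ring. The brighter ZmSMC1 probe was lower in pre-meiotic cells by a log2 ratio of -0.71 ± 0.102 (1.63-fold, limma adjusted p = 0.00356), lower on both arrays, while the other stood at 0.01 and was not called. Of 4 ZmSMC3 probes, the brightest was not called, with a log2 ratio of 0.02 and opposite signs on the arrays, and the other 3 were lower at -0.64, -0.79 and -0.88 (limma adjusted p = 0.00521, 0.00245 and 0.00243). Under median centring in place of loess, the uncalled ZmSMC1 and ZmSMC3 probes turned to -0.71 and -0.73 and were called lower (limma adjusted p = 0.0299 and 0.0421), while the called ones lay between -1.63 and -1.41. With processed signals all 4 called probes lost the call at similar ratios, -0.74 to -0.95 (limma adjusted p = 0.0773 to 0.099). The fit to processed signals had little power, as stated for AM1, so this says little. Without the offset the called ZmSMC1 probe and 1 ZmSMC3 probe lost the call (limma adjusted p = 0.0572 and 0.064). With the dye in place of the array the ZmSMC1 probe and 2 ZmSMC3 probes lost it (limma adjusted p = 0.0886, 0.0691 and 0.0572), and the ZmSMC1 probe lost it whichever of the 4 samples was left out (limma adjusted p = 0.0529 to 0.0905). Of the 3 called ZmSMC3 probes, 2 lost the call when some of the samples were left out. None of the 6 tested probes of ZmRAD21, the kleisin subunit of cohesin, passed the threshold in limma, and 0 had an unadjusted p under 0.05. The brightest ZmRAD21 probe had a log2 ratio of -0.28 ± 0.192, and 2 others were well above background in whole anthers only. Their fitted folds were 1.07 and 1.06 towards whole anthers and were not called (limma adjusted p = 0.538 and 0.607). The lower bound on the fold equals these fitted folds, so it shows no difference beyond them. Processed signals gave 3.23-fold and 2.14-fold for the same probes. With processed signals 1 ZmRAD21 probe was called lower, and with median centring another was. ZmSGO1, a shugoshin that protects centromeric cohesion, stood at 0.06 ± 0.102 (limma adjusted p = 0.716).

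**Figure D1:**
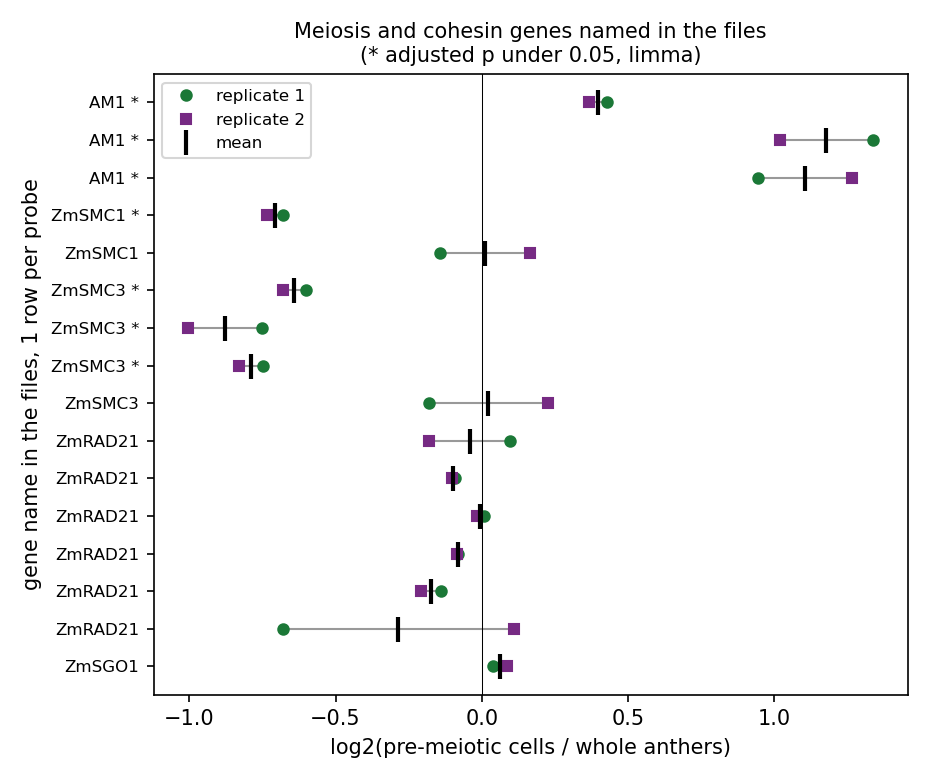
Log2 ratio of pre-meiotic cells over whole anthers (x axis) for each tested probe of AM1, ZmSMC1, ZmSMC3, ZmRAD21 and ZmSGO1 (1 row per probe). Circles are replicate 1, squares replicate 2 and bars their mean, and a star marks probes called by limma: all 3 AM1 probes lie right of 0, and the called ZmSMC1 and ZmSMC3 probes lie between -0.64 and -0.88, while the ZmSMC1 and ZmSMC3 probes near 0 turned negative under median centring.

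As a list, the 10 meiosis and recombination probes of 4 genes did not move one way. Of these, 3 were higher (all AM1) and 4 lower (ZmSMC1 and ZmSMC3), and 3 and 4 when adjusted over the list alone. The median log2 ratio was 0.02 although camera gave the direction as down, with p = 0.872 in limma's camera (p = 0.894 with an estimated correlation). limma's fry, which does not compare the list with other genes, gave p = 0.131 for a shift in one direction and 0.0253 for change in either direction. With ZmRAD21 added, a choice made after the data were seen, camera gave p = 0.602 (p = 0.773 with an estimated correlation).

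AI676903, listed as the protein-coding gene LOC100279569 in the reference table, was higher in pre-meiotic cells by 0.83 ± 0.103 (1.78-fold, limma adjusted p = 0.0021) on both arrays. Its ratio fell to 0.10 with median centring (limma adjusted p = 0.703) and 0.26 with it over the tested probes (limma adjusted p = 0.335). With processed signals, where a lost call says little, it stood at 1.11 and was not called (limma adjusted p = 0.0607). It also lost its call with the dye in place of the array (limma adjusted p = 0.0627) and without pre-meiotic cells replicate 1 or 2 (limma adjusted p = 0.0539 and 0.0705). Of the 4 probes with names of the MuDR type, after the transposon that drives the Mutator family, 0 passed the adjusted threshold in limma and 2 had an unadjusted p under 0.05. Their log2 ratios ran from -0.37 to 0.32, and the probes at both ends were called when limma's variance prior followed intensity. Those calls carry little weight, since that fit gave implausibly small values (limma adjusted p = 7.92e-274 for the sequence BE512404). With median centring the lower MuDR-type probe was called at -1.14 (limma adjusted p = 0.00458), and the upper one turned to -0.09 and was not called.

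Across all probes, 5092 were higher and 6567 lower in pre-meiotic cells (limma with Benjamini-Hochberg adjustment), 34.65% of the 33646 tested. Large differences lay mostly on the lower side, but the sides are not alike by design. Whole anthers also contain the pre-meiotic cells, which caps how far a transcript can be higher in those cells. A transcript lower in them has no such cap. Of the tested probes, 1059 were at least 2-fold higher and 2104 at least 2-fold lower on average with the same sign on both arrays. Without the offset of 50 the 2-fold counts were 2618 and 5024, and with processed signals 4288 and 7355. With median centring they were 135 and 5723, and 252 and 4503 with it over the tested probes. In the main processing the numbers at 4-fold were 46 and 440, and at 8-fold they were 1 and 122. The tested probes included 139 that were well above background in pre-meiotic cells only and 1504 in whole anthers only. In the main processing the most strongly raised sequences were TC307993, higher by 3.04 ± 0.107 (8.22-fold), and TC289279, higher by 2.71 ± 0.112 (6.54-fold). The most strongly lowered were BE512404 at -5.76 ± 0.149 (54.2-fold lower) and TC280505 at -5.64 ± 0.133 (49.8-fold lower), all called by limma and each with 1 sign on both arrays. With median centring the log2 ratios of TC307993 and TC289279 fell to 2.26 and 1.95 and those of BE512404 and TC280505 stood at -6.51 and -6.36. With processed signals the 4 stood at 3.42, 3.38, -6.40 and -6.08 (10.7-fold, 10.4-fold, 84.2-fold and 67.5-fold). In those signals 2 AM1 probes, at 3.91 and 3.75, lay above both raised sequences, so the ranking depends on the processing. The log2 ratios of both arrays correlated at 0.875 across probes. The SD between replicates of a probe, dye effects included, was 0.226 against SDs of 0.625 and 0.652 across probes.

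The split of calls depended on the processing within arrays. Loess gave 56.3% of calls on the lower side, and 62.5% without the offset (3061 higher and 5103 lower). Median centring gave 724 higher and 10614 lower (93.6%), and median centring over the tested probes (chosen after seeing the data) 1582 and 9094 (85.2%). The scanner's processed signals, median-centred, gave 1070 and 2851 (72.7%). These signals were already lowess-normalized and differ in background handling too, so their share cannot be put down to normalization alone. Median centring moved the median of all tested probes to -0.15, from -0.0085, and median centring over the tested probes put it at 0.01, so the shift of the median alone does not account for the split. A separate-channel fit without the pairing gave 3596 higher and 4975 lower with all 4 samples, and 1487 to 1875 higher and 1939 to 3072 lower when any 1 of them was left out.

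**Figure D2:**
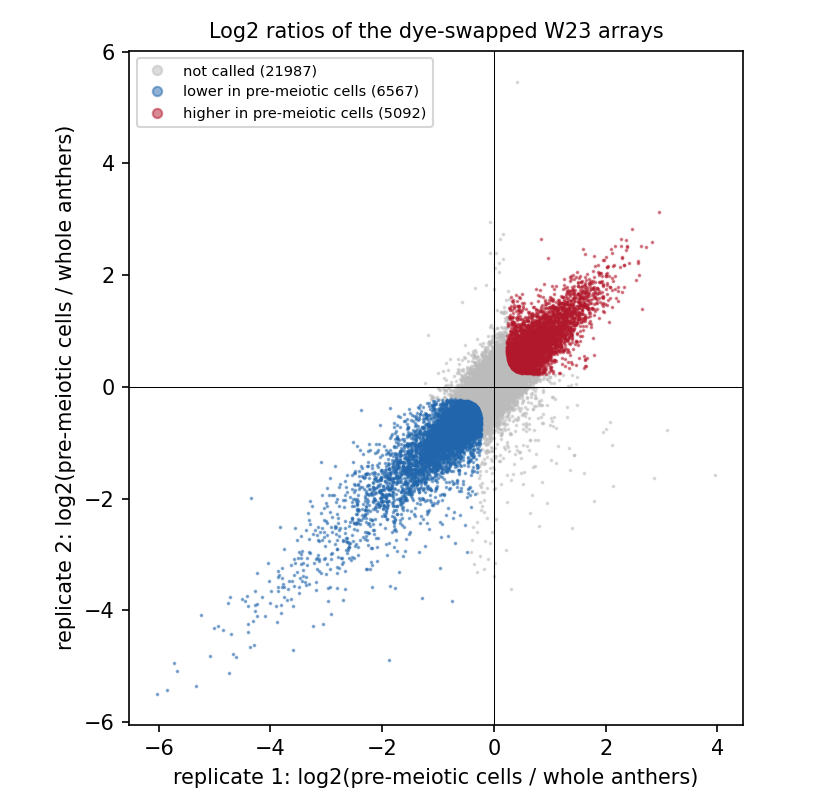
Log2 ratio of pre-meiotic cells over whole anthers on replicate 1 (x axis) and on the dye-swapped replicate 2 (y axis) for the 33646 tested probes. Red points are the 5092 probes called higher in pre-meiotic cells, blue points the 6567 called lower and grey points those not called; the arrays correlate at 0.875 and the lower side reaches further from 0.

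The second comparison asked how pre-meiotic cells differ without normal mac1 function. No measured probe of the named meiosis and cohesin genes reached a 2-fold difference between mac1 mutant and heterozygote cells, although 2 ZmRAD21 probes did with processed signals, at -1.54 and -1.26. The AM1 probes had log2 ratios of mutant over heterozygote from -0.18 to 0.23 and the ZmSMC3 probes from -0.40 to -0.19. The ZmSMC1 probes stood at -0.02 and -0.18, 4 measured ZmRAD21 probes lay between -0.20 and 0.02, and ZmSGO1 stood at -0.05. The median of the 10 meiosis and recombination probes was -0.18, at percentile 5.05 of random lists, which describes these libraries only, and -0.35 with median centring. The random lists drew separate probes, while several probes of this list share a gene, so the percentile may be too extreme. With processed signals the AM1 probes lay between -0.61 and 0.29, the ZmSMC3 probes between -0.62 and -0.49 and the ZmRAD21 probes between -1.54 and 0.99, the ZmSMC1 probes stood at -0.24 and -0.43, and ZmSGO1 at -0.28. AI676903 stood at 0.02, and at 0.08 with processed signals. The MuDR-type probes lay between -0.21 and 0.25, and between -0.88 and 0.70 with processed signals.

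Of 32266 measured probes, 252 were at least 2-fold higher and 179 at least 2-fold lower in the mutant, together 1.34%, and the SD of all log2 ratios was 0.293. Which side was larger depended on the processing: without the offset 1602 were higher and 1955 lower, with processed signals 2415 and 4767, and with median centring 176 and 289. The highest were TC311854 at 2.76 (6.77-fold) and TC280229 at 2.72 (6.57-fold). Both were lower in W23 pre-meiotic cells than in whole anthers, TC311854 by a log2 ratio of -5.33 ± 0.190 (limma adjusted p = 7.95e-05) and TC280229 by -2.32 ± 0.116 (limma adjusted p = 0.000171). The sequences most strongly lowered in W23 pre-meiotic cells went the other way on the mac1 array, BE512404 at -1.25 and TC280505 at -1.66. The lowest in the mutant by the main processing were CF059868 at -3.28 (9.71-fold) and TC307708 at -3.27 (9.63-fold). These sizes depend on the processing: without the offset TC311854, TC280229, CF059868 and TC307708 stood at 2.996, 3.83, -4.65 and -3.71, and with processed signals at 2.96, 4.08, -5.12 and -3.82. On the W23 arrays the pre-meiotic over whole log2 ratios of TC307708 were 2.14 and -1.78, and those of CF059868 were 0.30 and -3.61. The whole-anther samples of opposite dye differed most, with an SD of log2 intensity of 2.55 for TC307708 and 3.10 for CF059868 against 0.211 and 0.331 in pre-meiotic cells. The mean red over green ratio there was -1.96 for both, and subtracting it left -1.31 for TC307708 and -1.32 for CF059868. Dye and replicate differences are mixed in that mean. A dye effect would part samples of opposite dye in both groups, but the pre-meiotic samples differed little. For these probes the mean is therefore a poor estimate of the dye effect, and the subtraction does not show that dye made them low. After that subtraction they were no longer the lowest, since TC280505 stood at -1.865 and BE512404 at -1.512. There is no replicate and no dye swap of this comparison, so genotype, dye and sample cannot be separated, and no probe named mac1 was there to check the labels.

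Set against each other across 29954 probes, the comparisons were nearly unrelated, with a Pearson correlation of -0.0819 and a Spearman correlation of -0.0576 (probes are not independent replicates). With median centring the Pearson correlation turned to 0.0418. The median mutant over heterozygote log2 ratio was -0.0669 for the 5088 probes called higher in W23 pre-meiotic cells and -0.0030 for the 6240 called lower, against -0.0096 for all. Among probes at least 2-fold higher in the mutant, 28 were called higher and 130 lower in pre-meiotic cells; among those at least 2-fold lower, 54 were called higher and 64 lower. Over all probes, the mac1 heterozygote correlated with W23 pre-meiotic cells at 0.956 and 0.962 and with whole anthers at 0.898 and 0.901, and the mutant at 0.947 and 0.955 and at 0.898 and 0.896. Replicates correlated at 0.982 for W23 pre-meiotic cells and 0.981 for whole anthers, and mutant and heterozygote, on 1 array, at 0.981.

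**Figure D3:**
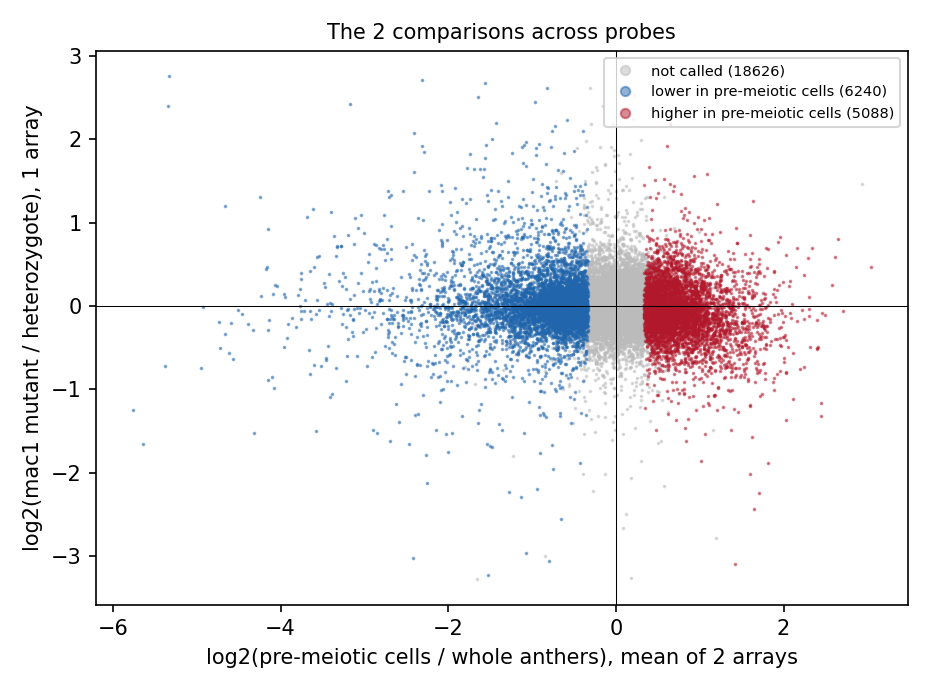
Mean log2 ratio of pre-meiotic cells over whole anthers (x axis, 2 arrays) and log2 ratio of mac1 mutant over heterozygote (y axis, 1 array) for probes measured in both. Red, blue and grey points are probes called higher, called lower and not called in pre-meiotic cells; the correlation is -0.0819, and 0.0418 with median centring.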

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

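The test of whether strongly lowered transcripts moved together on the mac1 array, the shifts a weak relation needs, and the use of the spread between single arrays were chosen after the result was seen. Some positive-control features of the array, whose identity the files do not give, carried signal although no comparison used them. Of the 18 features named DCP, 16 were well above background in all 6 samples, and of the 13 named ETG, 1 was. By comparison, 0 of 12 features named RC and 0 of 153 negative-control spots were.

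The first pattern was the set of probes at least 2-fold different between mac1 mutant and heterozygote cells. After the mean red over green ratio per probe of the swapped W23 arrays was subtracted as an estimate of the dye effect, 79.3% of these probes were still at least 2-fold different the same way, just short of the 80% set beforehand as the bound against dye bias. The counts rose with it, from 252 to 292 higher and from 179 to 201 lower, but subtracting a noisy value adds probes past 2-fold whatever the cause. The estimate also holds replicate differences, since each orientation has 1 replicate, and the mac1 dyes were not swapped, so dye bias cannot be told apart from the other explanations. A difference due to genotype stays open and untested, as do differences between single dissections.

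The second pattern was the weak negative relation between the comparisons. The correlation was 0.0418 with median centring and -0.0132 with processed signals, so its sign depended on the normalization and there may be no relation to explain. If the mutant cuts held more somatic cells, probes called higher in pre-meiotic cells would fall and those called lower would rise. Those calls came from 700 µm W23 anthers, while the mac1 anthers were 1 mm long. The medians of the called groups lay at -0.0572 and 0.0066 from that of all probes. Both are within the 0.1 set beforehand as the bound against this explanation. A relation this weak needs shifts of only -0.0251 and 0.0287, so that bound was too wide. The shift of the higher group was larger than needed and that of the lower group smaller. The SDs of single members (0.346 and 0.396) do not measure how well a median is known, which a single array cannot give. Of the called probes at least 2-fold higher in the mutant, 130 were lower and 28 higher in pre-meiotic cells. The correlation kept 145.5% of its size after the red over green mean was subtracted, which lies above the 80% set against dye bias by less than the SD of 0.0552 between single W23 arrays. That mean and the W23 ratios come from the same arrays, so subtracting it can move the correlation whatever the mac1 array holds. The test therefore cannot decide on dye bias. Of 122 probes at least 8-fold lower in pre-meiotic cells, 10 were at least 2-fold higher and 6 at least 2-fold lower in the mutant, so 62.5% lay on the commoner side (exact 95% interval 35.4% to 84.8%), but the lower side was the commoner after the red over green subtraction (9 and 10), with median centring (5 and 9) and with processed signals (20 and 35). Their median was -0.0363, or -0.0266 from that of all probes. More somatic cells in the mutant cuts would need a rise of 0.135 to give this relation. The SD of single members was 0.709, and a single array gives no measure of how well this median is known. Somatic cells, dye bias, the choice of normalization and the untested genotype therefore cannot be told apart.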

How the results depend on the processing

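Median centring over the tested probes and the addition of ZmRAD21 to the list were chosen after the result was seen. Signal over background limits dim probes, and Aquantile scaling moved no ratio. The counts of called probes, 5092 higher and 6567 lower, kept within 1.5 times without background correction, with the deposited value table, with either other filter, with either other variance prior, with intraspot correlation, and with no replicate block (3596 and 4975, a fit without the pairing that changed the call of none of the named probes). They moved to 3061 higher with normexp at offset 0, 1070 and 2851 with processed signals, 724 and 10614 with median centring, and 1582 higher with median centring over tested probes, where the 9094 lower stayed within 1.5 times. The fit with dye in place of the array, which pairs samples crosswise, gave 1298 and 2039. Leaving out 1 sample from the fit with no replicate block, with the lone sample assumed to vary like the others, gave 1487 to 1875 higher and 1939 to 3072 lower (1875 and 3072 without whole anthers replicate 1, 1487 and 2763 without replicate 2, 1532 and 2417 without pre-meiotic cells replicate 1, 1541 and 1939 without replicate 2), against its 3596 and 4975 with all 4 samples.

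Counts at 2-fold in the W23 comparison, 1059 and 2104, became 2618 and 5024 with offset 0, 4288 and 7355 with processed signals, 135 and 5723 with median centring, and 252 and 4503 with it over tested probes. On the mac1 array, 252 and 179 became 1602 and 1955 with offset 0, 2415 and 4767 with processed signals, and 289 lower with median centring. The correlation of the comparisons was -0.0132 with processed signals and reversed to 0.0418 with median centring, and lay between -0.119 and -0.0411 on single W23 arrays. The meiosis list stayed uncalled, and its mac1 median moved from -0.18 to -0.35 with median centring. Offset 0 widens ratios of dim probes by construction; for the other changes the cause was not tested.

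The uncalled ZmSMC3 probe reversed to -0.73 with median centring and -0.57 with it over tested probes, and the uncalled ZmSMC1 probe to -0.71 and -0.55. Other named probes of the W23 comparison kept their sign where called; 32 of their values under alternatives lost the call and 7 gained it. On the mac1 array, 30 values of named probes moved by more than the spread between W23 replicates, most of them with processed signals or offset 0.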

Other observations

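All tests in this part were chosen after the result was seen. Probes for transcripts that were far lower in pre-meiotic cells than in whole anthers were also more often at least 2-fold different on the mac1 array. Of the 122 probes at least 8-fold lower, 13.1% were at least 2-fold different between mutant and heterozygote, against 1.36% of the other 29832 probes measured in both. Within 10 bins of intensity on the mac1 array the odds ratio was 7.28 (95% interval 4.15 to 12.8). That interval treats probes as independent, although the mac1 values come from a single array without a replicate. The share was 9.61 times that of the other probes, but 2.02 times with processed signals (45.1% against 22.3%), 7.71 times with median centring (11.5% against 1.49%) and 9.93 times after the red over green mean of the W23 arrays was subtracted (15.6% against 1.57%). These probes went both ways, with 10 higher and 6 lower, but 9 and 10 after that subtraction, 5 and 9 with median centring and 20 and 35 with processed signals. Their median log2 ratio was -0.0363.

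Among called probes, 1240 named by a single sequence accession were higher and 760 lower in pre-meiotic cells (62% higher), against 3820 and 5781 of those named by a cluster of sequences (39.8% higher). Single-accession probes were dimmer (median log2 intensity 6.26 against 7.07), but lower intensity is argued against as the cause, because within 10 bins of intensity the odds ratio was 2.74 (95% interval 2.47 to 3.03), against 2.47 without that matching. The lowest odds ratio over the other background, signal and normalization settings was 2.74. Loess and median centring differ by a shift that depends on intensity, which matching on intensity largely removes. The matched odds ratio therefore cannot decide whether the choice of normalization caused the pattern. Other filters and variance priors gave 2.65 to 2.73, and separate-channel fits were not run for it. The interval treats probes as independent, although all of them share the same W23 arrays. No biological explanation was tested, nor was an effect of the different sample preparation, and the pattern was found and tested on the same data.

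Of 247 sequence names with at least 2 called probes, 22 (8.91%) had calls in both directions, which limits what a single probe says of its gene.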
